A study of Escherichia coli with 6 samples.

How the data were processed

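Chromatin immunoprecipitation with exonuclease digestion was carried out, per the labels' protocols, on Escherichia coli K-12 MG1655 strains whose OxyR, SoxR or SoxS carried an 8myc tag, with 1 anti-myc antibody. Of the 6 samples, 5 had a file and were analysed: 2 of OxyR, 2 of SoxR and 1 of SoxS (replicate 2). SoxS replicate 1 was not analysed here. No input or untagged library was used here.

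Per the submitters' processing notes, reads were aligned with Bowtie 1.0.0 and the build was named ASM584v2. The counting tool and the treatment of reads with several alignments are not given in the sources used here. The deposited signal is coverage, the number of aligned reads over each position on each strand, with no normalization and with uncovered positions left out. All deposited values were whole numbers of at least 1. Each rise in coverage was followed by an equal fall 31 positions later, so the 5' ends of 31-nt reads were recovered from the coverage, and 0 negative counts arose in each library.

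The numbering of the files was checked against a gene table of the assembly ASM584v2. Copies of repeated elements share reads, so their distances can be read from the files alone. Of 28 copies searched, 26 were found (correlation of at least 0.55, next best match at most 0.18), and all 26 lay 776 to 1978 bp from where the table puts them relative to the start of the chromosome. The files therefore do not use the numbering of that table, although the submitters' processing notes name the same build. Placing genes by the measured displacements was tried and then withdrawn as a conversion between builds. No gene was placed on the files' positions, and every position given is that of the files, on the single chromosome, whose last listed position was 4639673. The gene-start windows, the gene lists and the rule for named genes that had been fixed before the data were examined could for this reason not be used as written. Bins of 200 bp took the place of gene-start windows, a choice made after the data were seen, and no gene list was tested. Motif content was not tested, since no genome sequence was used here.

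Signal of both strands was averaged over 23198 bins of 200 bp and divided by the local background of the library, the median of 200-bp bins within 25 kb either side. Differences were tested on log2(fold over background + 0.1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend, two-sided moderated test, Benjamini-Hochberg adjustment over all bins, threshold 0.05). All 5 libraries entered 1 fit with a coefficient for each factor. The spread came from the OxyR and SoxR pairs, and the lone SoxS library was assumed to vary like them. A log2 difference on this scale understates differences of bins near 0. Called bins of 1 direction within 200 bp were joined into a region, which is described by its bin of largest difference. Named in the text are the 10 peaks of highest fold of each factor and regions among the 10 of largest difference in each direction, with further peaks chosen after their values were seen.

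Peaks were 100-bp windows, every 50 bp, with signal at least 5 times the local background in every library of the factor. Passing windows within 200 bp were merged and ranked by the mean fold of the highest window. A peak is called 2-fold specific where, at its highest window, every library of its factor was at least 2 times the highest library of the other factors. Overlaps of at least 1 bp were set against 1000 random circular shifts. The border on each strand was the position with most read 5' ends within 150 bp of the middle of the highest window. A peak was taken to lie in repeated sequence where its base-by-base pattern of 5' ends over 300 bp at the highest window occurred again elsewhere with a correlation of at least 0.5, which was so for 4 of 200 random positions. This check was revised after a first version without removal of the peak's outline had marked sharp peaks. It marked 7 OxyR, 12 SoxR and 11 SoxS peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

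The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Over windows of 1000 bp, chi-square per degree of freedom for distinct 5' ends was 1.08 between the OxyR and 0.95 between the SoxR replicates, against 5.16 to 24.32 between factors. Independent counts would give 1 with an SE of 0.021, but a position holds at most 1 distinct end, so sampling alone would give a value below 1. The OxyR replicates thus differed by at least slightly more than sampling noise. For the SoxR replicates, 0.95 does not settle whether they did. Reads differed by more (2.76 and 7.92). Replicates shared 24.2% (OxyR) and 13.6% (SoxR) of the distinct 5' ends of the smaller library, while random parts of equal size of 1 library shared 43.6% to 86.8%. The pairs were therefore not 1 library deposited a second time and were kept as 2 replicates. Reads carry no molecular identifiers, so reads with the same 5' end may be amplified copies of 1 molecule.

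On simulated data with the spread of OxyR against SoxR, limma recovered 0 of 50 planted differences of 0.5, 8 of 50 of 1, 40 of 50 of 2 and 48 of 50 of 3 on the log2 scale, and made 4 calls among 22998 bins with no planted difference, over 23198 bins. Every simulated library had the same spread within a bin, whereas over 200-bp bins the real replicates correlated at 0.832 (OxyR) and 0.681 (SoxR). The 4 calls therefore do not measure the error rate of the real comparison. Peak calling on simulated OxyR libraries found 0 of 50 planted 3-fold sites and 50 of 50 at 8-fold. For simulated SoxR libraries it found 0 of 50 at 3-fold, 44 of 50 at 8-fold and 50 of 50 at 15-fold. Neither simulation gave a peak outside the planted sites, but both spread background 5' ends evenly and capped the reads per end. They therefore cannot show how many peaks an uneven background or strong amplification would give. Calling from 1 library, as for SoxS, was not simulated. Alternatives tried were other pseudocounts, scalings, filters, spreads, peak thresholds, merging distances and overlaps, a replicate block, each replicated library left out in turn and, added after the data were seen, each 5' end counted once, bins offset by 100 bp and peaks in repeated sequence left out.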

Results

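The binding of 3 regulators of the oxidative stress response was mapped in E. coli K-12 MG1655 grown in minimal medium with 0.2% glucose and treated for 20 min with 250 uM paraquat, a redox-cycling compound that produces superoxide. OxyR is a LysR-type regulator that responds to hydrogen peroxide. SoxR is an iron-sulfur protein that responds to redox-cycling compounds and activates transcription of soxS, and SoxS is an AraC-type activator. Cells were crosslinked with 1% formaldehyde for 25 min, and DNA bound to the myc-tagged protein was trimmed by exonuclease before sequencing, which leaves a border on each strand of a crosslinked site. The comparisons ask where each regulator was enriched and which sites they share.

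The OxyR libraries held 2322443 and 3546490 recovered reads with 1322382 and 1190460 distinct 5' ends. The SoxR libraries held 1629802 and 1707081 reads with 300531 and 265639 distinct ends, and the SoxS library held 2647802 reads with 443936 distinct ends. Reads per distinct 5' end were 1.76 and 2.98 for OxyR, 5.42 and 6.43 for SoxR and 5.96 for SoxS. The median 200-bp bin held 89.4 and 137 reads in OxyR, 46.7 and 49.8 in SoxR and 70 in SoxS. Values for OxyR and SoxR are means ± SD with n = 2, and those for SoxS come from 1 library with no replicate. Positions are those of the deposited files. Their numbering differs from that of the gene table at hand, so sites are given by position and not by gene.

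OxyR was enriched at 63 peaks that covered 22.2 kb of the chromosome. The site at 2561251-2561600 was the highest, at 25.5 ± 0.87 fold over local background, followed by 3889451-3889650 (24.5 ± 1.2), 2922101-2922600 (20.7 ± 0.78), 2562901-2563450 (20.3 ± 1.5) and 3948251-3949000 (19.9 ± 0.74). The sites at 637751-639300 (19.6 ± 0.63), 296351-296550 (17.7 ± 0.073), 4156251-4156550 (15.8 ± 0.027), 83051-83800 (14.2 ± 0.6) and 262001-262200 (13.6 ± 0.59) completed the 10 highest. Those at 296351 and 262001 lay in repeated sequence, where reads of different copies cannot be separated. Those at 2561251 and 2562901 had a best correlation elsewhere of 0.42 each, under the bound of 0.5 but above the median of 0.26 at random positions. Of the 10, the peak at 4156251-4156550 was the only one where both OxyR libraries (15.7 and 15.8) exceeded every other library at the highest OxyR window. SoxR held 10.1 and 7.81 fold there, and SoxS 2.33. Within the same interval, the SoxR peak at 4156251-4156500 reached 18.2 ± 0.43 fold at its own highest window, where OxyR held 9.48 and 10.8.

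A total of 8 OxyR peaks were 2-fold specific. The highest was at 3670251-3670550, at 9.81 ± 0.84 fold. The site at 4603651-4603800 reached 7.03 ± 1 fold, 889901-890150 reached 6.39 ± 0.48 and 3667301-3667450 reached 6.14 ± 0.73. The other 4 lay close together between 79151 and 82300, with 7.28 ± 0.34 fold at 80851-82300. The rule compares folds only at the window highest in OxyR. The peak at 4603651 overlapped a SoxS peak that reached 30.7 fold at its own highest window, and that at 889901 overlapped SoxR and SoxS peaks. Over 200-bp bins at these 2 sites, SoxS (5.35 and 4.72 fold) was close to OxyR (5.71 ± 0.92 and 5.04 ± 0.21). With each 5' end counted once, the same rule was met at 2 of the 63 peaks, both among the 8, and the number of OxyR peaks was 7. Both counts are limited by saturation, since each position then holds at most 1 end. The limit is lowest for the OxyR libraries, which had the most distinct ends.

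SoxR was enriched at 210 peaks over 105.5 kb, with a steep order among the highest. The region 4274801-4275850 reached 1049 ± 84 fold, against 4.89 and 4.37 in the OxyR libraries and 27 in SoxS at the same window. At their own highest windows in this region, OxyR had a peak of 12.1 ± 1 fold (4274951-4275450) and SoxS 1 of 65 fold (4275051-4275600). The site at 3889201-3889900 followed at 618 ± 20 fold, and was also enriched in SoxS (174) and OxyR (23.7 and 25.4). Next came 2922051-2922650 (124 ± 9.5), 169551-170150 (121 ± 8.4), 637951-640650 (88.1 ± 3.3), 2716601-2717450 (70.1 ± 2.9) and 847451-848400 (68.6 ± 0.91). The peaks at 2509201-2510900 (61.4 ± 3.4), 3948201-3948700 (59.8 ± 3.7) and 4131751-4134400 (50.9 ± 4.5) completed the 10 highest. Of the 210 peaks, 36 were 2-fold specific, among them 565251-565650, at 42.4 ± 9.1 fold against at most 1.92 in OxyR and 1.37 in SoxS, and 4049001-4049350, at 24.3 ± 0.67. Without SoxR replicate 2, the number of SoxR peaks was 319.

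SoxS was enriched at 377 peaks over 192.8 kb in its single library. The highest was 3889201-3889850 at 174 fold, a site that ranked 2 in SoxR and 2 in OxyR. The region 4098451-4099600 reached 76.7 fold, against 5.87 and 5.33 in OxyR and 11.6 and 11.4 in SoxR. The peaks at 2561201-2561750 (76.2 fold), 2922051-2922650 (71.1), 4275051-4275600 (65), 3948151-3948750 (63.6) and 1989701-1990250 (61.9) came next. The 10 highest also held 296251-296700 (58.7), 261851-262350 (54.9) and 3939501-3945200 (52.6), of which those at 296251 and 261851 lay in repeated sequence, and the last holds a repeated SoxR peak at 3939551-3939750. By the same rule of size, 145 SoxS peaks were 2-fold specific, including 650601-651150 (49.5 fold), 1435151-1439150 (49.3) and 2309701-2311450 (48.8). With each 5' end counted once, 92 of the 377 peaks met the rule, of which 88 were among the 145. At a threshold of 3-fold the peaks numbered 144 for OxyR, 513 for SoxR and 969 for SoxS, and at 10-fold 13, 86 and 148.

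**Figure D1:**
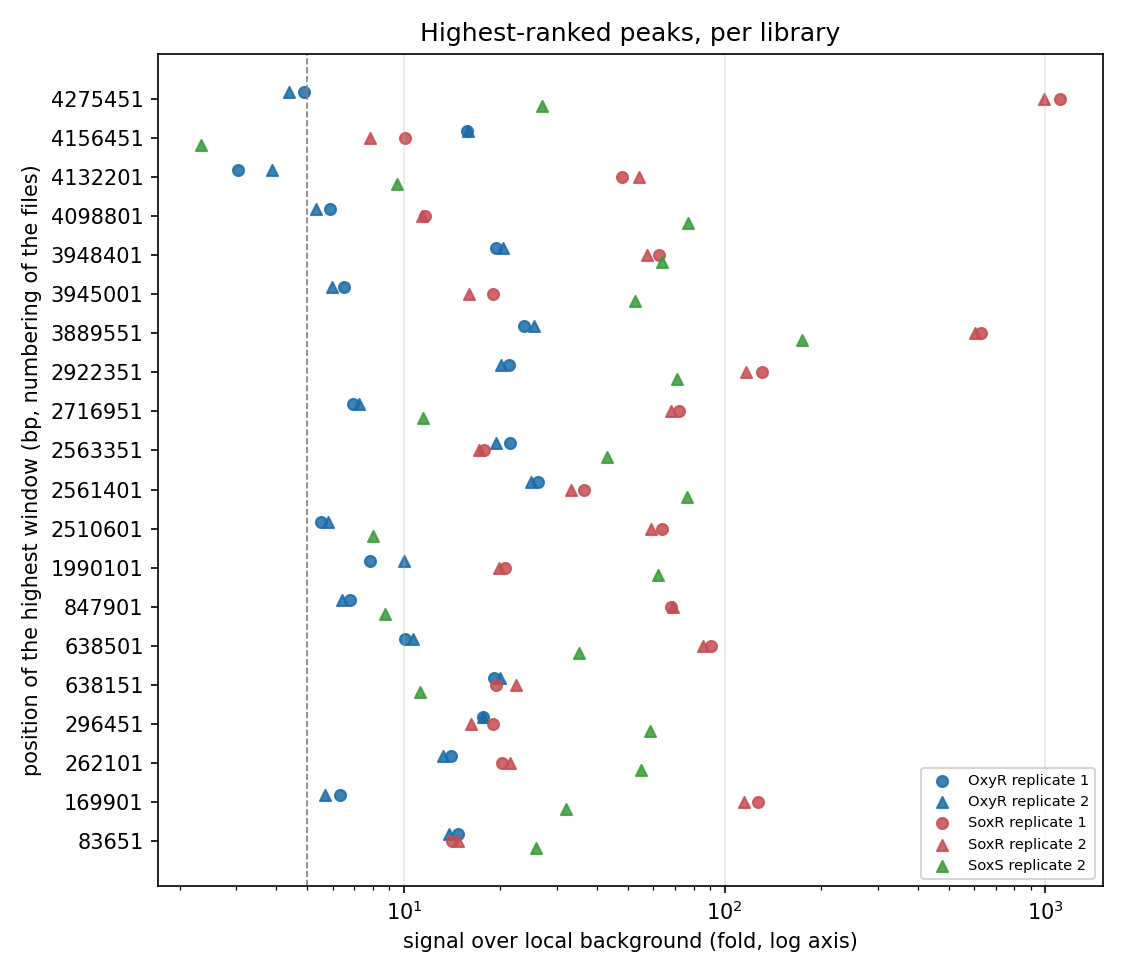
Signal over local background (fold, log axis) at the highest-ranked peaks of the 3 factors, by position of the highest window in the numbering of the files, with 1 point per library (circles replicate 1, triangles replicate 2, colors the tagged factor) and a dashed line at 5-fold. SoxR stands at 1049 ± 84 fold at 4275451, while OxyR and SoxS lie at 4.89, 4.37 and 27 fold there, and replicates of a factor lie close together at each site.

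Most OxyR peaks lay on peaks of the other regulators. Of 63 OxyR peaks, 53 overlapped a SoxR peak (2.3 on average in random shifts, permutation p = 0.001) and 55 overlapped a SoxS peak (4.3 in random shifts, permutation p = 0.001). Of 210 SoxR peaks, 168 overlapped a SoxS peak (16.4 in random shifts, permutation p = 0.001). Each p is one-sided and the smallest that 1000 shifts can give. Counted from the larger set of each pair, 48 of 210 SoxR peaks (22.9%) and 49 of 377 SoxS peaks (13%) overlapped an OxyR peak, and 163 of 377 SoxS peaks (43.2%) overlapped a SoxR peak. All 3 factors met at 51 OxyR peaks, where the median fold was 7.3 in OxyR, 17.6 in SoxR and 30.9 in SoxS. The 40 SoxR peaks that overlapped neither other factor had a median fold of 7.52 in SoxR, 1.83 in OxyR and 2.99 in SoxS, and the 210 SoxS peaks that overlapped neither had 6.21 in SoxS, 1.87 in OxyR and 2.89 in SoxR. Of the overlapping pairs, 39 (OxyR with SoxR), 39 (OxyR with SoxS) and 126 (SoxR with SoxS) had summits within 100 bp. The overlaps, in the same order, numbered 130 of 144, 142 of 144 and 402 of 513 with 3-fold peaks and 13 of 13, 12 of 13 and 70 of 86 with 10-fold peaks. With each 5' end counted once there were 7 OxyR peaks, and all 7 overlapped a SoxR and a SoxS peak.

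Peaks differed in width as well as height. The median width was 200 bp for OxyR, 300 bp for SoxR and 250 bp for SoxS, and 4, 22 and 45 peaks were at least 1000 bp wide. Wide SoxR peaks included 1759301-1762500 (34.8 ± 2.6 fold), 2657501-2660300 (28.1 ± 1.6) and 4131751-4134400 (50.9 ± 4.5). None of them was marked as repeated, but the check covered only 300 bp at the highest window. The widest SoxR peak, 3421401-3427000 (5600 bp), and the SoxS peaks at 3421351-3427050, 223451-229100 and 4033251-4038750 lay in repeated sequence. The widest SoxS peak, 2722451-2729550 (7100 bp), and the SoxR peak at 2724001-2729450 (5450 bp) hold the repeated OxyR peak at 2724451-2727000, though not at their highest windows. The median distance from the plus-strand to the minus-strand border was 39 bp for OxyR (interquartile range 19 to 80), 43 bp for SoxR (12 to 97) and 39 bp for SoxS (-13 to 84). At the 10-fold peaks the OxyR median was 64 bp. The plus-strand border lay to the left of the minus-strand border at 92.1% of OxyR, 79% of SoxR and 71.4% of SoxS peaks. Reads run rightward from plus-strand 5' ends and leftward from minus-strand ones, so centering on the window of highest coverage favors this order. Random windows were not compared, so the order and distances do not by themselves show borders left by the exonuclease.

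**Figure D2:**
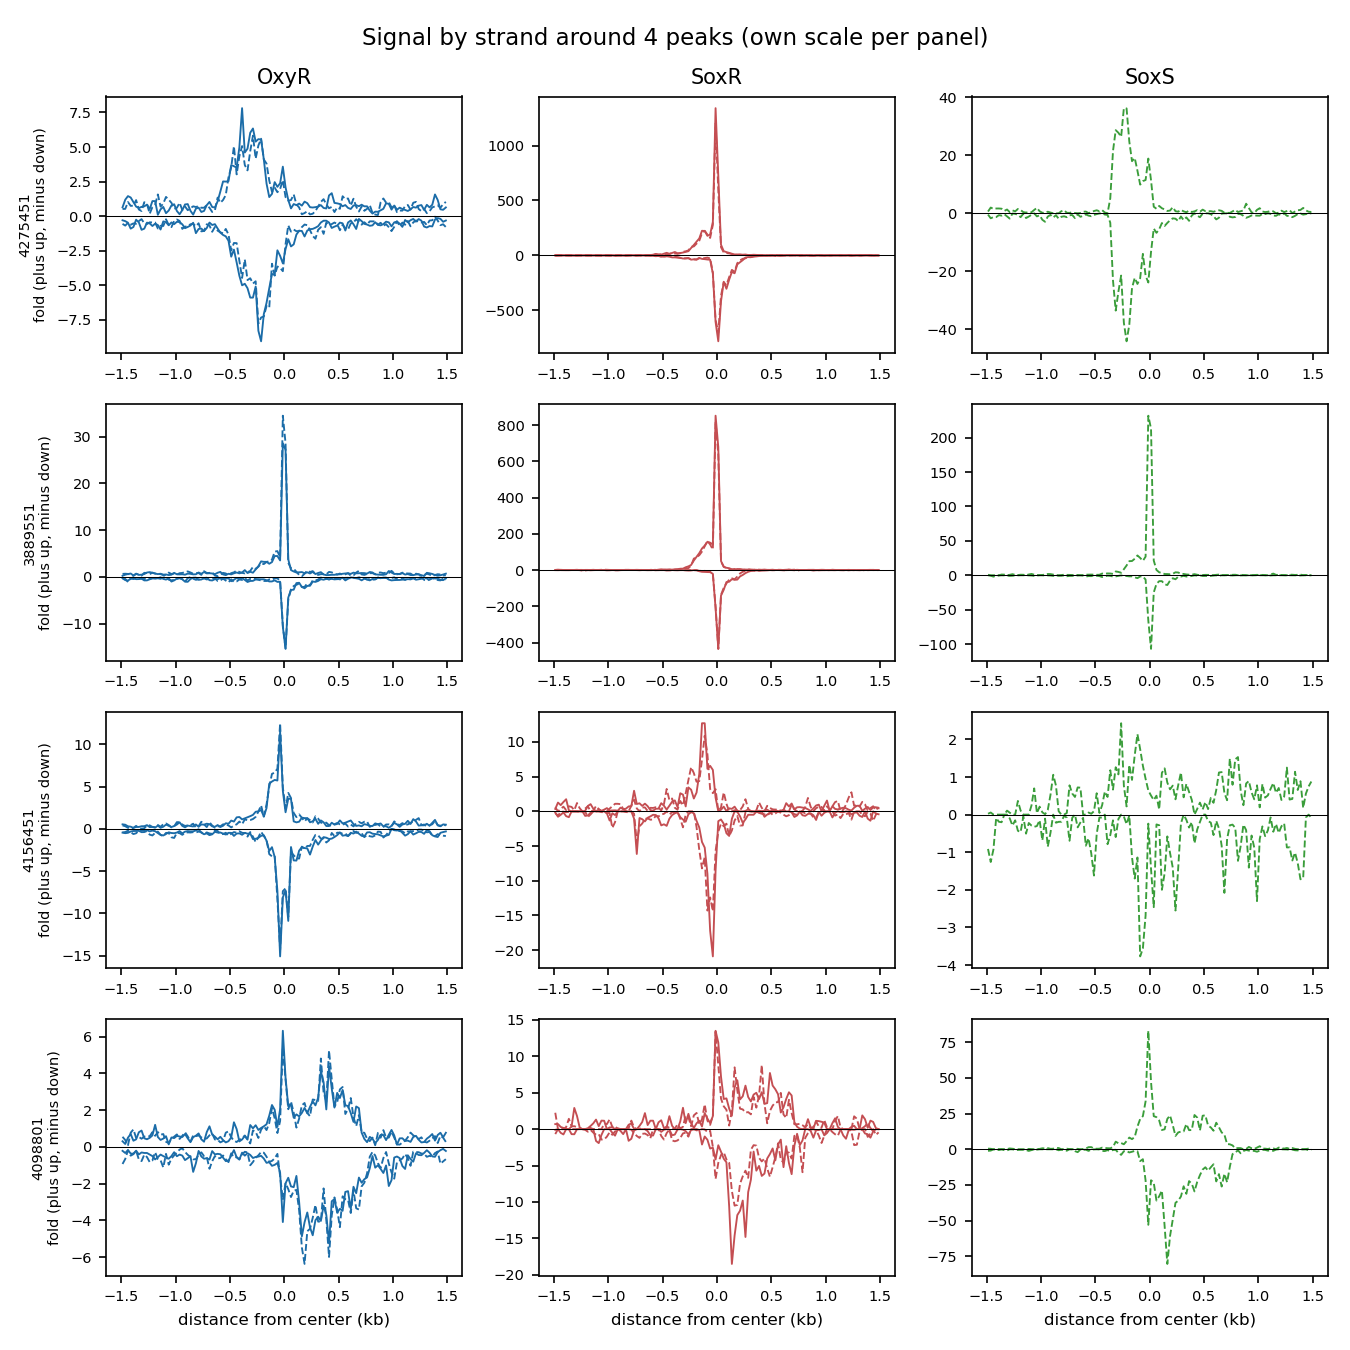
Coverage in 25-bp steps, as fold over the local background of both strands, on the plus strand (drawn upward) and the minus strand (drawn downward) within 1.5 kb of 4 peaks, with solid lines for replicate 1, dashed lines for replicate 2 and a scale of its own in each panel. At 3889551 the 3 factors have a sharp signal at the same place, and at 4275451 the highest SoxR signal (1049 ± 84 fold) lies to the right of the highest OxyR and SoxS signals.

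Between OxyR and SoxR, 976 of 23198 bins, which formed 365 regions, were higher in SoxR, and 67 bins, which formed 24 regions, were higher in OxyR (limma, adjusted p below the threshold of 0.05). This imbalance was not seen with either SoxR library left out. The spread then came from the OxyR pair alone, whose libraries correlated more closely than the SoxR pair (0.832 against 0.681 over 200-bp bins). A lone SoxR library is thereby judged by the spread of OxyR, so these fits cannot tell whether the imbalance holds. At 4274801-4276400, the bin of largest difference held 646 ± 50 fold in SoxR and 3.45 ± 0.3 in OxyR, a log2 difference (OxyR minus SoxR) of -7.51 (SE 0.09, limma adjusted p = 1.8e-07). The region 3889201-3890000 followed at -4.69 (SE 0.06, 381 ± 14 against 14.7 ± 0.7), then 565201-565600 at -4.51 (33.7 ± 4.1 against 1.4 ± 0.36), 169601-170200 at -4.23 (74.7 ± 4.3 against 3.88 ± 0.31) and 2736601-2739400 at -4.06 (16.3 ± 0.75 against 0.894 ± 0.18). The next were 4131801-4134400 (-3.52), 1987601-1989200 (-3.46), 1018201-1020000 (-3.36), 2508801-2510800 (-3.29) and 2656801-2660400 (-3.25). Of the 365 regions, 204 were single bins and 56 were at least 1000 bp long. A SoxR peak lay in 182 of them and not in the other 183.

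The largest difference toward OxyR was in the region 78601-83600, 5000 bp long, where a bin held 6.05 ± 0.33 fold in OxyR and 0.839 ± 0.54 in SoxR (log2 2.84, SE 0.39, limma adjusted p = 0.0089). The region 2068801-2069400 held 3.77 ± 0.25 against 0.483 ± 0.26 (log2 2.80). In 311401-312200 and 1939201-1941600, OxyR was above SoxR (3.17 ± 0.23 against 0.454 ± 0.12, and 5.14 ± 0.43 against 0.866 ± 0.34) while SoxS stood higher still, at 11.3 and 9.63 fold. The other 6 of the 10 largest were single bins with OxyR near background and SoxR far below it, such as 2962401-2962600 (0.875 ± 0.18 against 0.0507 ± 0.072) and 398601-398800 (0.908 ± 0.031 against 0.0743 ± 0.041). Those at 2962401 and 398601 were not called without OxyR replicate 1 (limma adjusted p = 0.91 and 0.86) or OxyR replicate 2 (0.57 and 0.84), and without the trend in limma the bins of 78601-83600, 2068801-2069400 and 1939201-1941600 were not called (adjusted p = 0.082, 0.059 and 0.061). Of the 24 regions, 8 held an OxyR peak. Scaled to total signal in place of local background, which moved the median of all bins from 0.02 to 0.37, the calls were 237 bins higher in OxyR and 639 higher in SoxR, without the trend they were 14 and 118, and with each 5' end counted once SoxR was higher in 1574. Leaving out OxyR replicate 1 gave 42 and 582 bins and OxyR replicate 2 gave 41 and 607.

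If the single SoxS library is assumed to vary like the OxyR and SoxR pairs, limma called 1031 bins (365 regions) with more signal in SoxS than in OxyR and 58 bins (39 regions) with less. The spread of SoxS itself was not measured, and these counts depend on the assumed spread, since without the trend limma called 0 bins in either direction (4050 at an unadjusted p under 0.05). The region 2736601-2739400 held 23.3 fold in SoxS and 0.959 ± 0.016 in OxyR (log2 4.47), and SoxR was enriched there as well (13 ± 0.33). It was followed by 1320801-1321200 (9.72 against 0.663 ± 0.049, log2 3.69), 1214601-1215200 (16.9 against 1.25 ± 0.13, log2 3.66), 4098401-4099600 (65.4 against 5.19 ± 0.49, log2 3.63) and 650601-651200 (16.2 against 1.31 ± 0.18, log2 3.53). The region 81001-83400 held 0.882 fold in SoxS and 5.54 ± 0.41 in OxyR (log2 -2.52), and the other 9 of the 10 largest differences toward OxyR were single bins near background in OxyR and far below it in SoxS. Scaled to total signal, which moved the median of all bins from 0.04 to -0.43, 649 bins were higher and 242 lower, and with each 5' end counted once 112 were lower. Leaving out OxyR replicate 1 or 2 left 15 bins lower in SoxS, and without SoxR replicate 1 or 2 there were 5073 or 5063 higher and 4013 or 4003 lower.

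Under the same assumption, limma called 321 bins (126 regions) with more signal in SoxS than in SoxR and 175 bins (74 regions) with less. These counts too depend on the assumed spread, since without the trend limma called 0 bins in either direction (3990 at an unadjusted p under 0.05), and with each 5' end counted once the numbers were 181 and 182. The region 311401-312400 held 11.3 fold in SoxS and 0.454 ± 0.12 in SoxR (log2 4.38), and 1939001-1941800 held 13 against 0.617 ± 0.054 (log2 4.19). In 2039401-2040600 the values were 13.3 and 0.923 ± 0.14 (log2 3.72), in 1214601-1215000 16.9 and 1.31 ± 0.031 (log2 3.59) and in 4098401-4099600 37.1 and 4.42 ± 0.14 (log2 3.04). The largest differences toward SoxR were at 4274801-4276000 (646 ± 50 against 16.9, log2 -5.25), 565201-565600 (33.7 ± 4.1 against 0.82, log2 -5.19), 1987601-1988800 (7.06 ± 0.91 against 0.426, log2 -3.76), 4131801-4134400 (27 ± 0.079 against 1.99, log2 -3.70) and 2657601-2660200 (13.3 ± 1.4 against 1.12, log2 -3.46). SoxS was higher in 502 bins with the genome-wide background and 574 with the filter at background, while SoxR was higher in 283 with total signal and 279 with the filter. Leaving out SoxR replicate 1 or 2 gave 5535 or 5113 bins higher in SoxS and 4341 or 4176 higher in SoxR.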

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

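Named bins kept their direction in each setting in which they were tested. Some were removed by the filter at background, and bins offset by 100 bp were compared by their counts alone. Without the trend, limma called 14 bins higher in OxyR and 118 higher in SoxR, and 0 bins in each direction for SoxS against OxyR (4050 at an unadjusted p under 0.05) and against SoxR (3990). All 20 named bins of each SoxS comparison lost their call there, as did 6 of 20 for OxyR against SoxR. Without OxyR replicate 1 or 2, 6 or 6 of the 20 named bins of OxyR against SoxR and 8 or 9 of those of SoxS against OxyR lost theirs, and 2 of those of SoxS against SoxR without either. For OxyR against SoxR, 5 of 20 were lost with the highest 100-bp mean, 5 with pseudocount 0.01, 4 with each 5' end counted once and 2 with the genome-wide background. For SoxS against SoxR, 3 were lost with the filter, 2 with each 5' end counted once and 1 with pseudocount 0.01, and for SoxS against OxyR 1 each with the highest 100-bp mean, pseudocount 0.5 and each 5' end counted once. The alternative "window 150 bp upstream" was not run, because no gene starts could be placed, and the gene list and motif alternatives were not run for the same reason or for lack of a genome sequence. Counting each 5' end once, offset bins and leaving out peaks in repeated sequence were chosen after seeing the data. The cause of the changes below was not tested unless stated.

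For OxyR against SoxR, the main counts were 67 bins higher in OxyR and 976 higher in SoxR. Scaling to total signal gave 237 and 639, and each 5' end counted once gave 1574 higher in SoxR. Leaving out a replicate gave 41 to 4680 and 582 to 4809. The high ends came without a SoxR replicate, where the spread is that of the OxyR pair alone.

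For SoxS against OxyR, total signal gave 649 higher and 242 lower (main 1031 and 58), and each 5' end counted once gave 112 lower. Leaving out a replicate gave 745 to 5073 higher and 15 to 4013 lower. For SoxS against SoxR, the genome-wide background gave 502 higher (main 321), the filter at background 574 higher and 279 lower (main 175), each 5' end counted once 181 higher and 182 lower, and total signal 283 lower. Leaving out a replicate gave 311 to 5535 higher and 156 to 4341 lower. Bins offset by 100 bp stayed within 1.5 times the main counts in each comparison.

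The replicate number as a block gave 227 bins higher in OxyR and 1590 higher in SoxR, 1610 higher and 185 lower for SoxS against OxyR, and 923 higher and 459 lower for SoxS against SoxR. Replicate differences of OxyR and SoxR correlated at 0.0031 across bins, with 2 pairs only, so the numbers are not taken to pair the libraries.

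At a 3-fold threshold there were 144 OxyR, 513 SoxR and 969 SoxS peaks, and at 10-fold 13, 86 and 148. OxyR peaks overlapping SoxR peaks were 130 at 3-fold and 13 at 10-fold, OxyR peaks overlapping SoxS peaks 142 and 12, and SoxR peaks overlapping SoxS peaks 402 and 70. With each 5' end counted once there were 7 OxyR peaks, of which 7 overlapped SoxR and 7 SoxS peaks. This count is limited by saturation, since each position can hold at most 1 end. SoxR peaks numbered 299 to 319 when a SoxR replicate was left out. The median border distance at 10-fold peaks was 64 bp for OxyR and 43 bp for SoxS. From single replicates it was 43.5 to 44 bp for OxyR and 37 to 38 bp for SoxR.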

Other observations

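The tests on repeated sequence and on a fixed proportion were chosen, or revised, after the result was seen. The other 3 were fixed before. At the 22 SoxR peaks of at least 1000 bp the median fold was 18.8 in SoxR, 4.62 in OxyR and 13.8 in SoxS, and at the 45 SoxS peaks of that width it was 16.6 in SoxS, 3.8 in OxyR and 7.41 in SoxR. The region 78601-83600 combined a wide tract in OxyR with 4 of the 8 specific OxyR peaks, and its part at 81001-83400 held 0.882 fold in SoxS against 5.54 ± 0.41 in OxyR at the bin of largest difference. At its right end, the peak at 83451-83900 had 25.8 fold in SoxS against 14.7 and 13.8 in OxyR. Genes under these tracts were not identified here.

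The 51 OxyR peaks on peaks of both other factors may reflect binding by the tagged proteins, or enrichment that any pulldown in these cells would give. Reads shared between repeated sequences do not account for most of them, since 13.7% had their pattern of 5' ends elsewhere, or 23.5% with the outline of the peak kept, as the check was first run. Amplification of few molecules would leave them flat with each 5' end counted once, yet 98% were then at least 2-fold over background in all libraries, against 1.79% of random windows. A signal present in 1 fixed proportion at all 51 peaks is not what the values show. The log2 ratio of SoxR to OxyR folds had an SD of 1.13 over these peaks, against 0.14 and 0.4 between OxyR and SoxR replicates. This ratio ran from -2.46 to 4.65, and the most extreme peaks weigh heavily in the SD. A common signal at a part of the 51 peaks was therefore not excluded. Enrichment unrelated to the tag stays open, whether common to a part of these peaks or varying between cultures, as no untagged library was used here.

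The larger number of peaks in SoxR (210) than in OxyR (63) might come from fewer, more amplified 5' ends. OxyR libraries thinned to the SoxR number of ends, with read numbers drawn from the SoxR libraries, gave 5 to 16 peaks over 20 draws. Thinning and random amplification of OxyR ends thus did not by themselves give as many peaks as the 210 of SoxR. The draws also discarded the OxyR libraries' own read numbers, and counting each 5' end once already left far fewer peaks than 63. Whether lower complexity raises or lowers the count of real sites can therefore not be told from these draws. A stronger enrichment in the SoxR strain, by its biology or by the pulldown, was not tested.

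The share of 2-fold specific peaks was 38.5% in SoxS, 17.1% in SoxR and 12.7% in OxyR, and SoxS peaks rest on 1 library. Calling the others from single libraries gave 26.3% and 25.4% for SoxR and 8.6% and 10.4% for OxyR. The highest of these, 26.3%, lies between the bounds set beforehand, so calling in 1 library, which may give a part of the excess, cannot be told apart from a difference between the factors. SoxS replicate 1 was not analysed here.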
